A study of Homo sapiens with 8 samples.

How the data were processed

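The series measured where 2 nuclear receptors of the estrogen-related receptor (ERR) family bind chromatin in SH-SY5Y, an established human neuroblastoma cell line. Chromatin immunoprecipitation with sequencing (ChIP-seq) recovers DNA fragments bound by the protein an antibody recognises, and peaks are the places where such fragments pile up. Per the labels, 8 libraries were made from untreated cells, 2 each of input DNA, ChIP with non-immune IgG, ERRα ChIP and ERRγ ChIP. Nothing in the labels says whether replicates came from separate cultures.

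The values used here came from a joint list of peaks deposited for the whole series, with a chromosome, a start, an end, a peak name and a score in each line. Reads were aligned with STAR 2.7.10a to hg38, per the submitters' processing notes. The peak names begin with MACS, the name of a peak caller, in the deposited list. The version of MACS, its threshold, the control library, the pooling of replicates and the step that brought the 2 factors into a single list are not given in the sources used here. No column marks a factor, a replicate or a library, so the list was treated as a single set of intervals and no value has a replicate error. The input and IgG libraries have no value of their own in the list, and no background could be set beside a peak. The list carries no read counts, so the depth of each library is unknown and intervals below cover only the counting of peaks and genes.

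The score in the deposited list is the authors' value for each named peak, on a scale the list does not name. It was used only to describe and rank peaks within the list. A name can stand on more than 1 interval, and each such interval then carries the same score.

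Intervals were set against the RefSeq gene table of assembly GRCh38, the build the submitters name. That table gives the start and the end of each gene, without strand, transcripts or sequence. The design fixed before the data were examined used transcription start sites, and these were replaced by both annotated ends of each gene, called the lower and the upper end by coordinate. An interval was near a gene end if its centre lay within 1 kb of either end of a protein-coding gene. Otherwise it was inside a gene if its centre lay between the ends, and outside genes if not. A window at a gene end holds the promoter at one end and the end of transcription at the other, and it can miss promoters that lie inside a long annotated gene. Exon, intron and untranslated-region classes, the 20 motifs fixed beforehand, a background matched on promoter base composition and the overlap of ERRα with ERRγ were not analysed here.

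The table also lists 32 protein-coding genes at low coordinates of the 5 acrocentric chromosomes, before a long gap, where no interval lies. Their positions are probably those of unplaced or alternate sequences and not of the chromosome. Genes listed in this way elsewhere were not identified, so more genes may be misplaced and wrongly counted as with or without a peak. The 32 genes stayed among the 19970 protein-coding genes, and the gap stayed in the span for random placement unless said otherwise.

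Shares of intervals were compared with 1000 random placements of the same intervals over the span of annotated genes of the same chromosome. The smallest p these can give is 0.001 for an excess and 0.002 for a two-sided comparison. Gene lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 18 lists and a threshold of 0.05. Shares have exact Clopper-Pearson 95% intervals, and odds ratios have 95% intervals from the log odds (Woolf). Scores were compared by a permutation test of ranks, two-sided, with 100000 permutations, for which the smallest p is 1e-05. Peaks and genes were the units of each test, not samples, so p-values describe the peaks and genes of this list. Neighbouring genes that share a peak are not independent.

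The 18 lists held 661 memberships, and all 661 matched a gene on the 23 chromosomes with intervals. They covered complex I, complexes II to IV with cytochrome c, ATP synthase, the tricarboxylic acid cycle with pyruvate dehydrogenase, fatty acid oxidation, the mitochondrial ribosome, and mitochondrial DNA maintenance, import and dynamics. Others covered mitophagy with autophagy and the lysosome, glycolysis, the ERR family with coregulators and metabolic transcription factors, the Wnt pathway, tau, amyloid processing with Alzheimer disease risk, noradrenergic identity, and the synapse. The cytosolic ribosome, the proteasome and genes of other tissues served for comparison. The genes named were chosen by a rule fixed before the data were examined. As fixed, it used transcription start sites and took the 10 highest peaks of each of ERRα only, ERRγ only and shared peaks. The list has no such classes, so the rule was applied to the whole list and to gene ends. It then took the nearest gene of each of the 10 peaks with the highest score and up to 6 members of each list by score. It also took 15 genes named with or without a peak. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be so where they appear.

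Alternatives were windows of 500 bp and 5 kb, the gene with the nearest end at any distance, all annotated genes in place of protein-coding ones, and the 10193 intervals with a score at or above the median. Further alternatives, chosen after seeing the data, counted each peak name once, kept random placements out of stretches of over 1 Mb without a gene, stratified genes by deciles of length (Mantel-Haenszel), left out genes with another gene end within 2 kb, used the whole gene body, and ranked scores within deciles of width. The test of gene lists was checked on simulated lists of 40 genes drawn from 19970 genes. With a planted share of 50%, 483 of 500 lists were called, and 21 of 500 lists drawn at random had an unadjusted p below 0.05. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.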

Results

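ERRα and ERRγ binding sites in SH-SY5Y neuroblastoma cells were described by a joint list of 20379 intervals on 23 chromosomes, given here in coordinates of GRCh38. ERRα and ERRγ are orphan nuclear receptors known as regulators of mitochondrial energy metabolism. The study had 8 libraries in 4 groups of 2, namely input DNA, non-immune IgG ChIP, ERRα ChIP and ERRγ ChIP. The intervals carried 19465 distinct peak names, of which 18605 stood on 1 interval and 860 on 2 or more. The median width was 257 bp (quartiles 196 and 339 bp), and the list covered 6.0 Mb in total. Peak numbers ran up to 70517, of which the listed names made up 27.6%, and widths went down to 1 bp. A width or a count is therefore that of listed intervals, which can be pieces of a called peak, and each piece carries the score of the whole. The score, the authors' value for each peak, ran from 3.53 to 223 with a median of 30.2 (quartiles 19.6 and 50.3). Because no interval was assigned to a factor or a library, a peak below is a binding site of the joint list, and no difference between ERRα and ERRγ or between replicates was analysed here.

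The first question was where in the genome the sites lie. Binding sites were concentrated at the ends of protein-coding genes. Within 1 kb of a gene end lay 3059 of the 20379 intervals, or 15% (95% CI 14.5 to 15.5%), 5.61 times the 2.68% found by random placement. Inside genes, farther from either end, lay 48.5% of intervals against 41.7% at random, and outside genes 36.5% against 55.6%. Random positions could fall in long gene-free gaps of any chromosome, which raises the random share outside genes. These 2 comparisons were not rerun without such gaps. Among 19970 protein-coding genes, 3204 (16.0%) had a peak at an end. Of these, 1539 had it only at the lower end, 1555 only at the upper end and 110 at both. Which end of a gene holds the promoter is not given in the gene table. A peak at an end of a gene named below is therefore not thereby a peak at its promoter. By permutation of positions, the excess near gene ends had p = 0.001 and the 3 classes p = 0.002 each, two-sided, the smallest values that 1000 placements can give. The enrichment was 7.75-fold with a window of 500 bp, 2.41-fold with 5 kb and 3.13-fold with the ends of all annotated genes, so its size depends on the window and the genes used. With all annotated genes, 24.5% of intervals lay outside genes. No random share outside genes was computed for that setting, so this value cannot be set against the 55.6%.

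**Figure D1:**
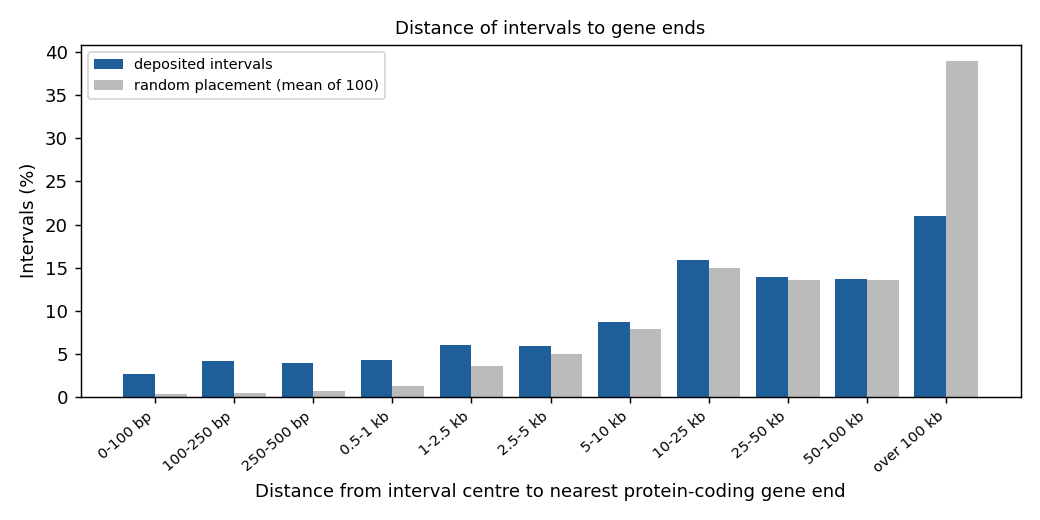
Share of the 20379 intervals (blue bars, percent on the y axis) by distance from the interval centre to the nearest protein-coding gene end (x axis, in bp and kb), beside the mean of 100 random placements (grey bars). The ratio of intervals to random placement is highest in the bins up to 1 kb, and 21% of intervals against 38.9% of random ones lie over 100 kb away. Random positions could fall in long gene-free gaps, which adds to the random share over 100 kb.

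The strongest sites included intervals at gene ends and intervals far from them. The highest score, 223, belonged to a peak on chromosome 13 at 99606687 to 99607114, 210 bp from an end of CLYBL, which encodes a mitochondrial enzyme. A peak with a score of 199 lay 433 bp from an end of ATP6V0B, a subunit of the vacuolar proton pump. The other 8 of the 10 highest peaks lay over 1 kb from the nearest protein-coding gene end. Their nearest genes were ERGIC1 (score 213), POTEF (205), PPP2R5E (204), RNF19B (202), RUNX3 (199), CDC73 (199), PTPDC1 (195) and SEMA6D (193). The distances ran from 8343 bp for RNF19B to 814761 bp for CDC73, so CDC73 is only the nearest gene on the map. POTEF belongs to a family of near-identical copies, so the position of its peak is uncertain.

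Sites near gene ends had higher scores than the rest. The median score was 37.3 (quartiles 24.4 and 61.8) for the 3059 intervals near a gene end and 29.0 (quartiles 18.8 and 48.7) for the 17320 others. Across all pairs of an interval near a gene end and another interval, the share in which the former scored higher was 0.603 (permutation test of ranks, p = 1e-05, the smallest value it can give).

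The next question was which groups of genes carry the sites, and within 1 kb of a gene end the 3 lists of oxidative phosphorylation had the highest shares. Complex I, the NADH dehydrogenase of the respiratory chain, had a peak at an end of 30 of 44 genes (68.2%, CI 52.4 to 81.4%). Complexes II to IV with cytochrome c had one at 24 of 36 genes (66.7%, CI 49.0 to 81.4%), and ATP synthase at 13 of 19 (68.4%, CI 43.4 to 87.4%). Other protein-coding genes had one in 15.9%, 16.0% and 16.0% of cases, respectively. The odds ratios were 11.3, 10.5 and 11.4, with adjusted exact p = 2.57e-13, 1.21e-10 and 2.84e-06 by Fisher's exact test over the 18 lists. The order depends on the assignment. With each peak given to the nearest gene end at any distance, the shares were 77.3% for noradrenergic identity and 76.7% for the tricarboxylic acid cycle, against 65.9%, 69.4% and 68.4% for these 3 lists.

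Over members with a peak, the median of the highest score at a gene end was 49.9 in complex I, 84.5 in complexes II to IV and 65.1 in ATP synthase. It was 66.5 in the mitochondrial ribosome and 76.3 in glycolysis, and the highest of the 18 lists was that of synaptic and excitability genes, which did not pass the test. The members named next are those with the highest scores of each list. ATP5MC3, a subunit of the membrane ring of ATP synthase, had a score of 190 at its upper end on chromosome 2, at 175180780 to 175182013. ATP5F1B, the catalytic β subunit, had a peak of 1055 bp centred 30 bp from its upper end (chromosome 12, 56645427 to 56646481, score 121). Scores at ATP5PD, ATP5PO, ATP5F1D and ATP5MG were 114, 80.3, 71.8 and 70.0. In complex I the highest scores were at NDUFS7 (143), NDUFB5 (131), NDUFB9 (121), NDUFAF4 (119), NDUFB4 (91.5) and NDUFA12 (78.9). In complexes II to IV they were at UQCRC1 (136) and CYC1 (108) of complex III, SDHD of complex II (103), COX7C (99.5) and COX4I1 (98.7) of cytochrome c oxidase, and UQCR10 (96.5). CYCS, the gene of cytochrome c itself, had no interval at its ends or inside it, and the nearest lay 54920 bp away. Some peaks lie within 1 kb of the ends of 2 genes and cannot be given to either, as with NDUFB5 and MRPL47, SDHD and TIMM8B, or COX4I1 and EMC8.

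**Figure D2:**
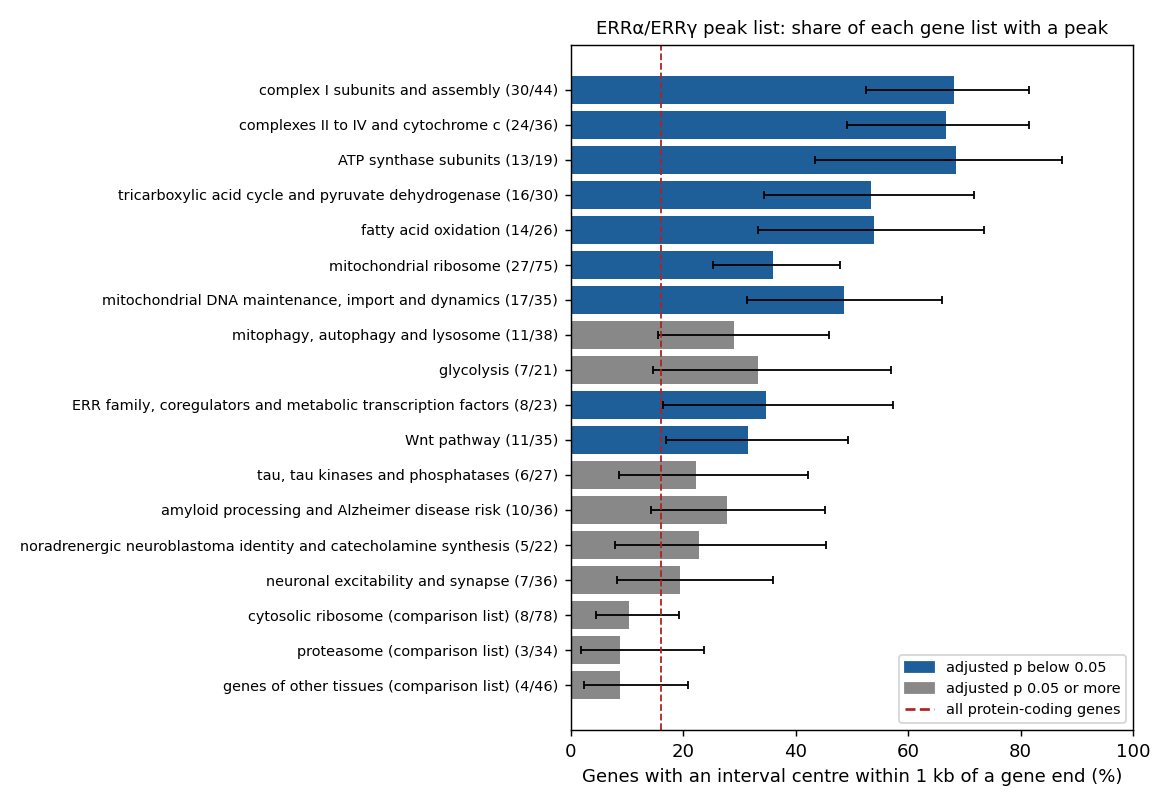
Share of the genes of each of 18 lists (y axis, genes with a peak over genes in the list) that have an interval centre within 1 kb of a gene end (x axis, percent), with exact 95% intervals as error bars and the 16.0% of all protein-coding genes as a dashed line. The 9 lists in blue passed an adjusted p of 0.05, and the 3 lists of oxidative phosphorylation lie at 66.7 to 68.4%.

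Fuel oxidation inside mitochondria showed the same direction. The tricarboxylic acid cycle with pyruvate dehydrogenase had a peak at 16 of 30 genes (53.3%, CI 34.3 to 71.7%, odds ratio 6.01, adjusted exact p = 1.26e-05). Fatty acid oxidation had one at 14 of 26 (53.8%, CI 33.4 to 73.4%, odds ratio 6.13, adjusted exact p = 3.08e-05). In the cycle, FH, which encodes fumarase, had a score of 124, and IDH3A, a subunit of NAD-dependent isocitrate dehydrogenase, had 109 at 78149432 to 78150432 on chromosome 15. SDHD had 103, SDHA 83.0 and DLAT 77.7, and SDHD and SDHA stand in both the cycle and the respiratory chain lists. In fatty acid oxidation, the scores were 141 at ECI1, 78.3 at DECR1, 57.4 at ETFB, 54.0 at ACADM, 50.6 at CPT1C and 42.6 at HADHA. ACADM, the medium-chain acyl-CoA dehydrogenase, had 2 intervals of a single peak at its lower end, and the HADHA peak, just inside HADHA, is also within 1 kb of an end of HADHB. CPT1A, which encodes the liver form of carnitine palmitoyltransferase, had no interval within 1 kb of an end but 3 inside, the strongest (score 136) 3330 bp from its upper end. PDK4, a pyruvate dehydrogenase kinase, had none at its ends or inside, and the nearest interval was 149721 bp away. Among genes with no other gene end within 2 kb, a restriction chosen after seeing the data, the fatty acid oxidation list had an odds ratio of 2.95 with adjusted exact p = 0.371.

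Genes that build and maintain mitochondria also carried peaks more often than other genes. The list of mitochondrial DNA maintenance, import and dynamics had a peak at 17 of 35 genes (48.6%, CI 31.4 to 66.0%, odds ratio 4.96, adjusted exact p = 2.61e-05). The highest scores there were at CHCHD3 (141), SLC25A5 (133), SLC25A4 (131), TOMM40 (113), IMMT (106) and HSPA9 (105). SLC25A4 and SLC25A5 encode the ADP/ATP carriers of the inner membrane, and TOMM40 the import channel of the outer membrane. The mitochondrial ribosome had a peak at 27 of 75 genes (36.0%, CI 25.2 to 47.9%, odds ratio 2.96, adjusted exact p = 5.77e-05). Scores were 168 at MRPS25, 148 at MRPL15, 143 at MRPL38, 131 at MRPL47, 118 at MRPL48 and 113 at MRPL34. When each peak was given to the gene with the nearest end at any distance, the odds ratio of the mitochondrial ribosome was 1.42 with adjusted exact p = 0.164.

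Glycolysis and the lysosomal pathway did not pass the test. In glycolysis, 7 of 21 genes had a peak (33.3%, CI 14.6 to 57.0%, odds ratio 2.62, adjusted exact p = 0.100). The peaks at ENO1 (score 159), TPI1 (143) and LDHB (118) scored high, while ALDOC had 76.3, PGK1 46.9 and GAPDH 25.2. The TPI1 peak lies near an end of USP5 as well. With a window of 5 kb the odds ratio of glycolysis was 2.96 and passed, with adjusted exact p = 0.0272. Mitophagy, autophagy and the lysosome had a peak at 11 of 38 genes (28.9%, CI 15.4 to 45.9%, odds ratio 2.14, adjusted exact p = 0.0775). Scores there were 52.1 at GABARAPL1, 41.9 at MITF, 39.0 at TFEB, 36.7 at ULK1, 31.6 at NPC2 and 29.7 at ATP6V0D1.

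Binding at the genes of the receptors themselves was a further question the list could address. ESRRA, which encodes ERRα, had 2 intervals of a single peak at its lower end on chromosome 11, at 64304404 to 64305286 and 64305427 to 64305638, with a score of 133. CATSPERZ also has an end there. ESRRG, which encodes ERRγ, had no interval at either annotated end but 15 inside its 634457 bp, the strongest with a score of 112 at 216580610 to 216581036 on chromosome 1. ESRRB, the third member of the family, had 5 intervals inside, the strongest with a score of 42.0, and none at its ends. The coactivator gene PPARGC1A and the corepressor gene NRIP1 had none at their ends or inside, with the nearest intervals 1441335 bp and 587803 bp away. The list of receptors, coregulators and metabolic transcription factors had a peak at 8 of 23 genes (34.8%, CI 16.4 to 57.3%, odds ratio 2.80, adjusted exact p = 0.0445). Besides ESRRA, scores were 79.1 at NCOA1, 65.2 at PPARA, 65.1 at GABPA, 56.6 at PPRC1 and 43.4 at THRA, and the GABPA peak is also within 1 kb of an end of ATP5PF. The call is close to the threshold and was lost with a window of 5 kb, at an odds ratio of 2.46 and adjusted exact p = 0.0607.

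**Figure D3:**
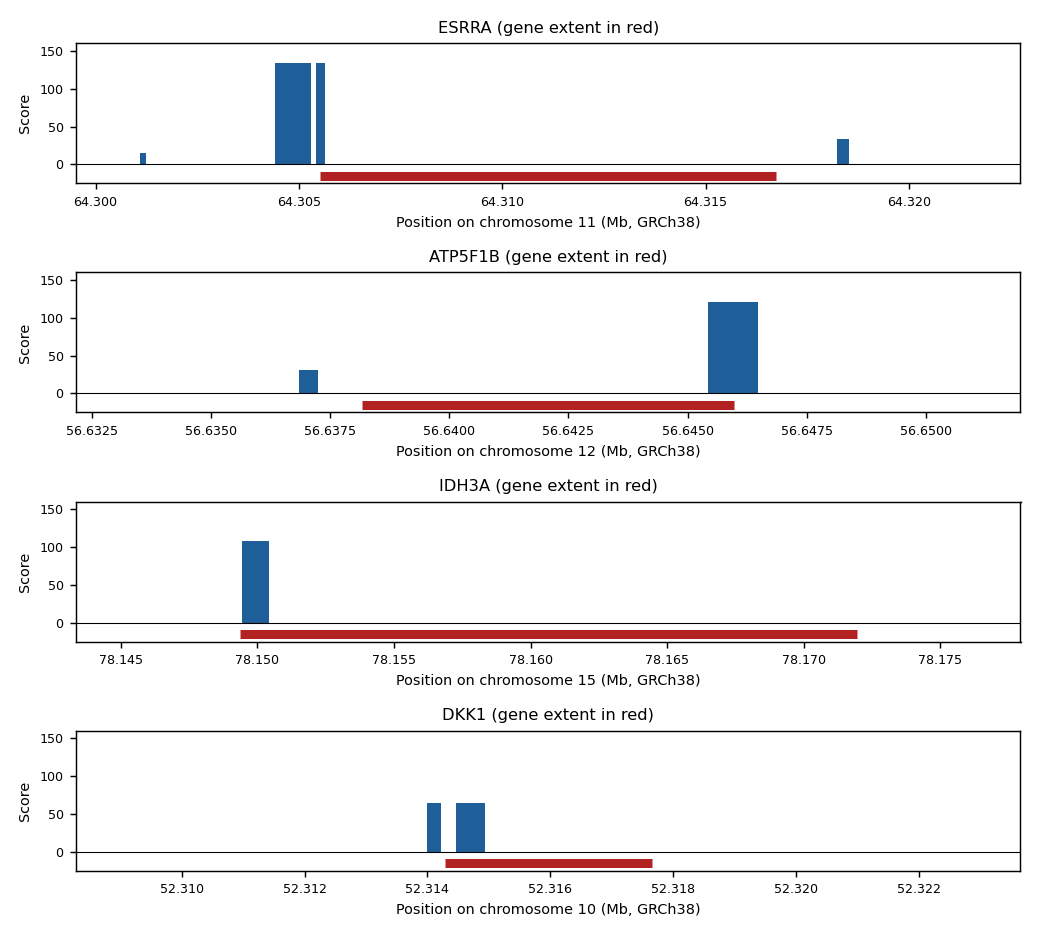
Intervals of the list (blue blocks, their height the score on the y axis) around ESRRA, ATP5F1B, IDH3A and DKK1, with the annotated gene extents in red (x axis, position in Mb, GRCh38). The highest intervals, with scores of 133, 121, 109 and 63.9, lie at or within 1 kb of a gene end in each panel.

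Wnt and neurodegeneration genes were examined because the lists were chosen for a neuronal cell line. Wnt pathway genes had a peak at an end in 11 of 35 cases (31.4%, CI 16.9 to 49.3%, odds ratio 2.40, adjusted exact p = 0.0445). FZD8, a Wnt receptor, had a score of 112 and the transcription factor gene TCF7 68.7. DKK1, a secreted Wnt antagonist, had 2 intervals of a single peak (score 63.9) at 52313995 to 52314215 and 52314464 to 52314935 on chromosome 10. DKK4 had 59.6, PORCN 46.4 and FZD4 45.3, with the DKK4 peak also near VDAC3 and the PORCN peak near EBP. The Wnt call was lost with a window of 5 kb (odds ratio 2.02, adjusted exact p = 0.0818) and among the 10193 intervals of higher score (2.19, adjusted exact p = 0.138). It was kept with the nearest gene end at any distance (odds ratio 3.37, adjusted exact p = 0.00217).

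Tau and amyloid genes had peaks in 22.2% and 27.8% of cases, and neither list passed. For tau, its kinases and phosphatases the count was 6 of 27 (CI 8.62 to 42.3%, odds ratio 1.5, adjusted exact p = 0.452), with scores of 84.4 at MAPK8, 35 at MAPK9, 26.9 at MARK1, 21.3 at PPP2CA and 19.4 at CSNK1D. MAPT, the tau gene, and GSK3B, a tau kinase gene, had no interval at their ends or inside, and the nearest lay 599841 bp and 120811 bp away. For amyloid processing and Alzheimer disease risk the count was 10 of 36 (CI 14.2 to 45.2%, odds ratio 2.02, adjusted exact p = 0.100). Scores there were 162 at the lower end of SPI1, 62.2 at APH1A, 48.5 at BACE1, 34.8 at BACE2, 33.0 at NCSTN and 28.1 at FERMT2. Whether the lower end of SPI1 holds its promoter is not given in the gene table. APP, the amyloid precursor gene, had 1 interval 102 bp from its upper end (score 26.6), and 8 inside counting that one, the strongest with a score of 61.8. Among the 10193 intervals of higher score the odds ratio of the tau list was 0.700, below 1, with adjusted exact p = 1.

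Genes of noradrenergic identity, which mark sympathetic neuroblastoma cells, passed the test with a window of 5 kb but not with 1 kb. Within 1 kb the count was 5 of 22 (22.7%, CI 7.82 to 45.4%, odds ratio 1.54, adjusted exact p = 0.430). The members were PHOX2A (54.7), DBH (44.2), TBX2 (34.1), HAND1 (23.5) and GATA3 (19.4), with the score in brackets. Within 5 kb the share was 68.2%, against 27.1% of other genes, with an odds ratio of 5.77 and adjusted exact p = 0.000251. The difference between the 2 windows was not tested. Synaptic and excitability genes had a peak at 7 of 36 genes (19.4%, CI 8.19 to 36.0%, odds ratio 1.26, adjusted exact p = 0.503). Scores were nonetheless 163 at the lower end of VAMP2 and 156 and 155 at the upper ends of RAB3A and CPLX1. These 3 genes act in synaptic vesicle release, and which end holds the promoter is not given in the gene table. SYT1 had 22.1 and KCNC1 13.5.

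Comparison lists of genes active in every cell and of genes of other tissues had low shares. The cytosolic ribosome had a peak at 8 of 78 genes (10.3%, CI 4.53 to 19.2%, odds ratio 0.597, adjusted exact p = 0.292). Its members with the highest scores were RPL26 (166), RPLP2 (79.9), RPL21 (45.2), RPL4 (44.0), RPS28 (40.1) and RPL11 (37.3). The RPL26 peak lies near an end of KRABD2 and the RPS28 peak near an end of NDUFA7. The proteasome had a peak at 3 of 34 genes (8.82%, CI 1.86 to 23.7%, odds ratio 0.506, adjusted exact p = 0.420), namely PSMA5 (31.6), PSMC1 (20.7) and PSMD8 (19.4). Genes of other tissues had one at 4 of 46 (8.70%, CI 2.42 to 20.8%, odds ratio 0.498, adjusted exact p = 0.292), namely TNNT2 (28.7), KRT10 (25.4), CKM (21.9) and MBP (11.7). None of these 3 lists passed the threshold with this window. When each peak was given to the nearest gene end at any distance, the cytosolic ribosome (odds ratio 0.461, adjusted exact p = 0.00879) and the genes of other tissues (0.427, adjusted exact p = 0.0325) passed as lower.

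The density of sites differed between chromosomes. Chromosome 17 had 13.1 intervals per Mb of annotated span, chromosome 19 had 11.1 and chromosome X 1.64, less than any autosome. Chromosome 21 had 3.30 per Mb, the lowest of the autosomes, and chromosome 7 had 8.79. The share of genes with a peak at an end was 20.7% on chromosome 7, 9.21% on chromosome 21 and 6.96% on chromosome X. The span of the 5 acrocentric chromosomes includes a long gap without genes, and counted above that gap chromosome 21 had 3.69 intervals per Mb and chromosome 22 had 12.1 in place of 9.59. No test was run on single chromosomes.

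**Figure D4:**
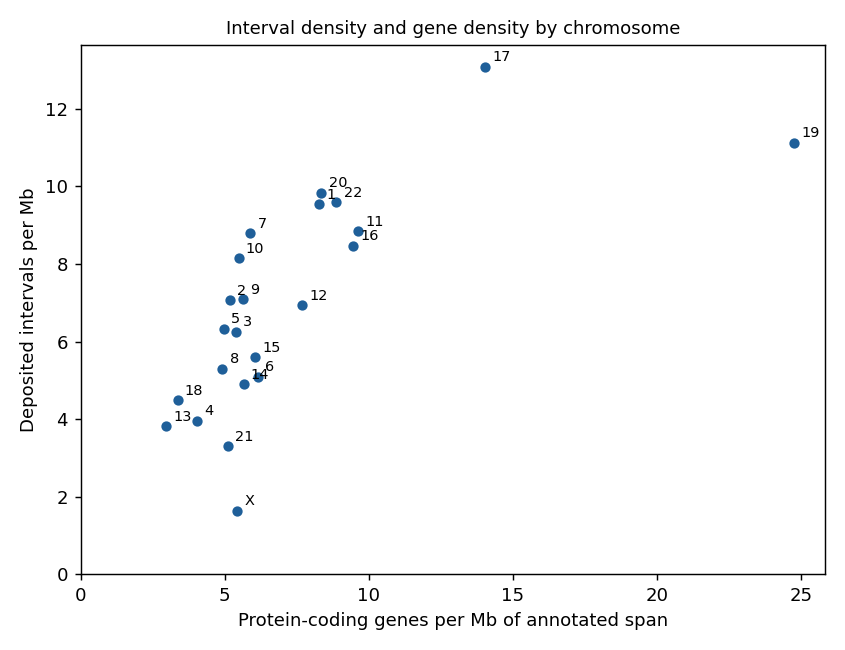
Intervals per Mb (y axis) against protein-coding genes per Mb of annotated span (x axis), with a point for each of 23 chromosomes. Chromosome 17 is highest at 13.1 intervals per Mb and chromosome X lowest at 1.64, with the gene-free gap of acrocentric chromosomes counted in their span.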

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

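Alternatives with a 5 kb window, the nearest gene end or the higher-scoring intervals were fixed before the data were examined, while the strata of gene length, the genes without another gene end within 2 kb, the whole gene body, names counted once, ranks within width deciles and the changed windows for single genes were chosen after seeing them. No paired analysis was possible because the list has no values per library, and for the same reason no replicate could be left out. Not run, for want of strand, transcripts or sequence, were the response-element alternatives, the background matched on CpG content, the limit to peaks with a response element and a single transcript per gene, and the overlap alternatives were not run because no interval names a factor. The depth of the libraries is unknown, so a gene without a peak is a gene without a listed interval and not one without binding. The enrichment near gene ends, the excess score there, and the calls of complex I, complexes II to IV, ATP synthase, the tricarboxylic acid cycle and mitochondrial DNA maintenance kept their direction and side of the threshold under each alternative run, with odds ratios from 2.78 to 26.0 for these lists. The enrichment near gene ends was 5.25-fold with gene-free stretches left out of random placement. The joint list fell to 10193 intervals at or above the median score, as that alternative sets it.

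In the other lists the odds ratios changed their call as follows, and the cause was not tested. With 5 kb the Wnt pathway (2.02) and the ERR family (2.46) no longer passed, while glycolysis (2.96) and noradrenergic identity (5.77) did. With the nearest gene end the mitochondrial ribosome (1.42) and the ERR family (2.40) no longer passed, while noradrenergic identity (5.25), the cytosolic ribosome (0.461) and genes of other tissues (0.427) did, the last 2 as lower. Among higher-scoring intervals Wnt (2.19) no longer passed, genes of other tissues had no peak (odds ratio 0) and passed as lower, and tau turned to 0.700. With length strata the ERR family had 2.56 and no longer passed. Among genes without a close neighbour the calls of fatty acid oxidation (2.95), the ERR family (2.95) and Wnt (1.48) were lost. With the whole gene body 16 lists passed in place of 9. It added glycolysis (4.17), tau (2.61), amyloid (2.09), noradrenergic identity (3.01) and synapse (2.33) as higher and the cytosolic ribosome (0.341), proteasome (0.277) and other tissues (0.312) as lower, and lost the mitochondrial ribosome (1.32). That count was not stratified by gene length, and a longer gene has more room for an interval.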

Other observations

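Tests chosen after the result was seen were those of name families, tRNA genes, divergent transcripts, noradrenergic genes one by one, the pooled oxidative phosphorylation genes and their pairs with other lists, open chromatin, extra chromosome copies, the arms without chromosome 7, and the arms with acrocentric gaps left out. Genes named in the first 2 paragraphs were chosen after their values were seen.

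Gene families were also defined by the start of the symbol. Of 81 families tested by Fisher's exact test against other protein-coding genes, 9 had peaks at gene ends more often and 5 less often after Benjamini-Hochberg adjustment. Of the higher families, NDUF, ATP5, COX, MRPS and MRPL largely repeat the fixed lists of the respiratory chain, ATP synthase and the mitochondrial ribosome. TMEM, a name shared by unrelated membrane proteins, had a peak at 61 of 233 genes (odds ratio 1.87, adjusted exact p = 0.000787). Coenzyme Q synthesis genes (COQ) had a peak at 7 of 11 genes (odds ratio 9.18, adjusted exact p = 0.00399), and TIMM genes of inner membrane import at 7 of 16 (odds ratio 4.08, adjusted exact p = 0.0470), of which TIMM23, TIMM44 and TIMM50 also stand in the fixed import list. Symbols beginning with KRT, which take in keratins and keratin-associated proteins, had a peak at 1 of 152, and those beginning with IL, interleukins and their receptors, at 2 of 85. Genes whose symbols begin with OR, the olfactory receptors, had one at 0 of 392, which allows a share of up to 0.765% if 3 genes are taken as the limit of a count of 0. Protocadherin genes (PCDH) had a peak at 26 of 65, but 4 distinct peaks lay behind them and 22 of the genes shared one. Among non-coding genes, tRNA genes had a peak in 13.1% of 443 cases, 32.4% of the 74 within 2 kb of a protein-coding gene end and 9.21% of the 369 farther away. For snoRNA genes the share was 0.920% of 1196.

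Several genes held long runs of sites in their bodies. MSI2, which encodes an RNA-binding protein, held 65 intervals in 446 kb, GSE1 63 in 507 kb, EXOC4 51 and SLIT3 38. ALK, a receptor kinase gene of neuroblastoma, held 28. Noradrenergic genes had 15 of 22 members with an interval within 5 kb of an end. GATA2 had one with a score of 176 at 4655 bp, ISL1 had 3 with a highest score of 72.1, and TH, which encodes tyrosine hydroxylase, had one of 65.2 at 3069 bp. MYCN had one of 30.9 at 3149 bp. Genes with a named divergent transcript, 593 in all, had a peak at the end facing that transcript in 20.2% and at the opposite end in 1.69%, a ratio of 12, with 119 genes at the facing end only and 9 at the opposite end only (exact binomial p = 1.21e-25).

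Peaks stood at the ends of 67 of 99 oxidative phosphorylation genes (67.7%, odds ratio 11.2, 95% CI 7.32 to 17). Open chromatin at promoters active in every cell would raise the ribosome and proteasome genes too, yet their odds ratio was 0.568 (CI 0.305 to 1.06), which argues against it as the whole account. Within strata of gene length the odds ratio was 12.0 (CI 7.83 to 18.3), and among genes with no other gene end within 2 kb 17.5 (CI 8.01 to 38.4), against compact genes or neighbours as the source. The mitochondrial ribosome lay between, at 36.0% (odds ratio of oxidative phosphorylation against it 3.72, adjusted exact p = 8.51e-05, and of it against the cytosolic ribosome 4.92, adjusted exact p = 0.000198). Preferential binding at these genes may be the account as a hypothesis, but no biological explanation was tested, since no control library or single factor has values here, and promoter base composition stays open.

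Interval density differed between chromosome arms. The arms 7p, 7q, 1q, 2p and 17q, taken as those with extra copies in SH-SY5Y, had on average 0.48 more on the log2 scale than the other 34 autosomal arms at the same length and gene number (exact permutation p = 0.00582 over 575757 regroupings), as extra copies could give. That test included chromosome 7, whose density had been seen. Without it the difference was 0.42 with p = 0.0502 (exact, 7770 regroupings). The call was thus lost with a difference of similar size and 3 named arms in place of 5. The smaller set cannot tell whether the call rests on chromosome 7. The gene-free gap of the 5 acrocentric chromosomes, all in the comparison group, was then left out of their length. The differences with and without chromosome 7 became 0.46 (exact permutation p = 0.00801) and 0.40 (exact permutation p = 0.0611). Of the named arms, 7p stood at 0.75, 2p at 0.58, 17q at 0.46, 7q at 0.23 and 1q at -0.01. Outside the set, 20q stood at 0.83 and 16q at 0.62, so extra copies stay open. Gene number with arm length narrowed the spread of log2 density by 37.0%, between the bounds set for and against it, so its part stays open too.

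Scores were higher near gene ends, with a share of pairs of 0.603. Wider intervals there could raise scores, since the median width was 275 bp near gene ends and 254 bp inside genes. Ranked within deciles of listed width, an alternative added after the data were seen, the share was 0.589. This argues against the width of listed intervals as the whole source. A listed interval can be a piece that carries the score of the whole peak, so the width of the called peaks stays open. The depth and control signal at these sites stay open, and no biological explanation was tested.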
